A study of Homo sapiens with 2 samples.

How the data were processed

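The series is a pooled CRISPR knockout screen in CAL27, a human squamous carcinoma line of the head and neck. Guides of the genome-wide Brunello library (76441 guides against 19114 genes, per the labels' protocols) were delivered by lentivirus at a multiplicity of infection below 0.3 to 20000000 cells of each of 2 lines, a PD-L1 knockout and its control. Per the same labels, cells were selected with puromycin for 2 days and passaged through 10 subcultures before genomic DNA was taken. The design text says that samples were done in duplicate, and the table used here holds 1 column per condition, so how duplicates were handled is not given in the sources used here.

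The deposited guide table gives, per guide and library, a signal that is never negative, made by the authors from guide counts with 1 scaling factor per library. Both columns sum to the same total. MAGeCK 0.5.9.5 and FastQC 0.12 are named in the submitters' processing notes, with no role or setting stated, and the aligner or matching rule for guides is not given in the sources used here. Whole reads were recovered by dividing each column by the value of 1 read, which is 0.974 in the control and 0.66 in the knockout library. All values above 0 (100% in each library) came out whole within a tolerance of 0.001 reads. The 1000 non-targeting guides are the only lines that name no gene (1.29% of lines). They were kept out of gene tests and served as a reference.

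The authors' deposited gene table is their comparison of the knockout with the control library. Per the file headers it holds, for each direction, a score, a p-value with its false discovery rate, a rank and a log2 fold change. It also gives the number of guides per gene. The headers do not name the method behind the score. The deposited log2 fold changes were set beside the median log2 ratios of guides with reads in either library: 17.1% of genes matched within 0.01 and the largest difference was 1.01, so the offset and scaling behind the deposited fold changes were not recovered here. Those values are used only as the authors' own.

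The gene test was fixed before the data were examined. For each guide, log2((knockout + 1) / (control + 1)) of the deposited normalized values was centred on the median guide and divided by the spread (1.4826 times the median absolute deviation) of guides of like mean abundance in 20 bins. Each score was limited to plus or minus 4. The gene statistic was the mean over its guides, with a two-sided permutation p from 2000000 random sets of as many guides, drawn with replacement, and Benjamini-Hochberg adjustment over genes at a threshold of 0.05. A guide was retained if its mean over both libraries was at least 10% of the median guide's mean (a normalized value of 14.7), and a gene was tested with at least 3 retained guides. Each condition has 1 library, so there is no replicate check, and the test compares these 2 libraries, not the conditions. The log2(value + 1) scale gives no true fold for a guide at 0 in 1 library, so reads are given in its place.

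The presence measure was added after the data were seen. A guide was called present at 20 reads or more, and a list's rates were compared as −ln(1 − share present), the mean number of founding units per guide if units fall on guides at random. Exact Clopper-Pearson intervals at 95% are given for shares. They count guides, not reads, and treat guides as independent draws, although guides of the same gene share its target. Error between cultures or libraries is not covered. Reads made by PCR without molecular identifiers are not independent molecules. A guide at 0 reads was taken to allow up to 3 reads of its library's total, a fixed setting that was not computed with these intervals.

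The 36 gene lists (918 entries) were fixed at the same stage as the test, and the 374 olfactory receptor genes, taken by symbol, made the list number 37. Of the entries, 7 were matched through an older symbol and 2 were not matched. Symbols were matched, and neighbours of CD274 found, with RefSeq gene names on GRCh38.p14, and no build is named in the files. For each list the median gene effect was placed among 10000 random lists of the same size matched on mean abundance, and the ratio of rates among 10000 random lists matched on the number of guides present over both libraries. For percentiles taken by library, the guides present in that library were placed among 10000 random lists of the same size, without matching. These percentiles describe the libraries and are not p-values. Selection within a library was taken as the area under the ROC curve that separates 6 essential lists from olfactory receptor and other unexpressed genes. The 6 are the large and small ribosomal subunits, proteasome, spliceosome, RNA polymerase II with its general factors, and DNA replication. A bootstrap interval of 1000 draws over genes is given. The 2 samples include no starting pool, so unequal starting amounts of guides cannot be told apart from selection.

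Genes named in the text were set by a rule: CD274, GPX4 and SOD2; members of the ferroptosis defence, selenoprotein, ferroptosis promotion and oxidant detoxification lists; 10 genes per direction from the gene test, filled by the smallest permutation p where too few passed; the first 10 per direction of the authors' ranking; and the members with the lowest and highest effect of every other list. Genes named outside it are said to be so. The table writes 1 gene name as a calendar date, and 2 names (MARCHF1 and MARCHF2) carry 8 guides each, so these 2 are uncertain and are not reported.

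As an added alternative, the recovered reads were summed per gene and compared with edgeR 4.0.16 in R 4.3.3 (exact test, library totals, common dispersion of 2.75 from 421 unexpressed genes taken as 1 group). It called 0 genes lower and 0 higher of 18822, with 7 at an unadjusted p under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

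The gene test, the list tests and the estimate of units were tested on simulated data that had the measured guide presence and read totals, with the spread between guides and between units assumed. With units as measured, 0 of 200 genes whose knockout rate was set to 0.25 and 0 of 200 genes set to 0 were called, in a step of 8863 tested genes. Of these, 34 and 17 had enough guides to be tested. With 100 times the units, 96% and 100% of them were called among 19103 genes, beside 0.174% of unchanged genes. With units as measured, lists of 20 genes at 0.5 of the rate fell below the lowest 2.5% of random lists in 47 of 100 cases by presence and 24 of 100 by log2 ratio, and 6 and 5 of 100 unchanged lists lay outside the central 95%. The units estimate came out 1.16 times the true number in the simulated control and 1.15 times in the simulated knockout library.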

Results

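The screen asked which gene knockouts are tolerated differently by CAL27 cells that lack PD-L1, the immune checkpoint ligand encoded by CD274, than by their control line. The series title places the interest in ferroptosis, a form of cell death driven by iron-dependent lipid peroxidation. Guide abundance after 10 subcultures was measured in genomic DNA of 1 library per line, so no value below has a replicate error. The control library held 20002143 reads and the knockout library 29507426 reads over the same 77441 guides, which target 19112 named genes with 4 guides each for all but 9 of them and include 1000 non-targeting guides.

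Most guides were missing from the control library, and many from the knockout library. In the control library 43460 guides had 0 reads (56.1%, 95% exact interval 55.8% to 56.5%), against 33851 in the knockout library (43.7%, 43.4% to 44.1%). Guides with at least 20 reads numbered 21654 in the control library (28.0%, 27.6% to 28.3%) and 38942 in the knockout library (50.3%, 49.9% to 50.6%). At least 1 guide was present for 13497 genes in the control library (70.6%) and for 17524 genes in the knockout library (91.7%). All 4 guides were present for 169 and 1605 genes. Median reads of a present guide were 760 in the control and 600 in the knockout library. The most abundant guide of the control library, against KCTD18, had 30232 reads (0.151% of the library), and that of the knockout library, against CPSF3L, had 7673 (0.026%). Both libraries shared 12922 present guides, where 10889 would be expected from independent presence (odds ratio 1.69). Across the guides present in both, log2 reads had a Pearson r of 0.0592 and a Spearman rho of 0.0582, taken across guides, which are not independent replicates.

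**Figure D1:**
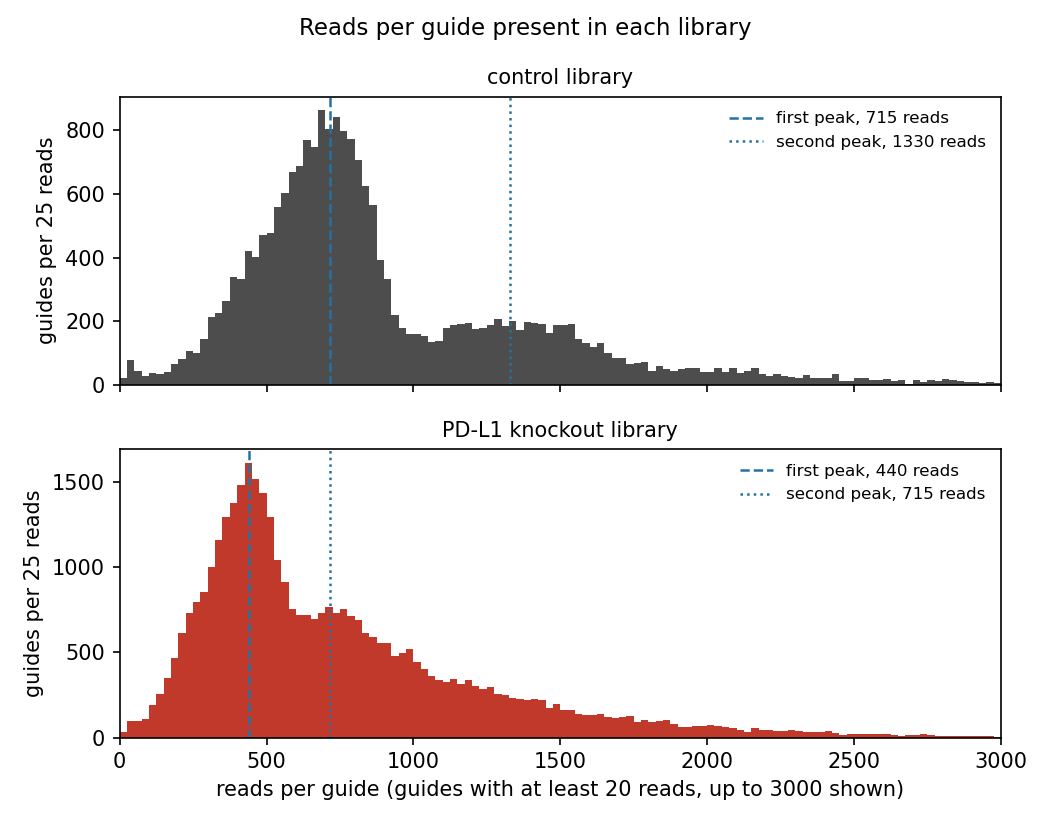
Number of guides (vertical axis, per 25 reads) by reads per guide (horizontal axis) in the control library and the PD-L1 knockout library, for guides with at least 20 reads, up to 3000 reads. The reads peaked at 715 and again at 1330 in the control library, and at 440 and 715 in the knockout library (dashed and dotted lines), and 173 and 155 guides with 3000 or more reads lie outside the plot.

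Guides against essential genes were scarcer than guides against unexpressed genes in both libraries. Of 812 guides against the ribosome, proteasome, spliceosome, RNA polymerase II and DNA replication lists, 13.5% were present in the control library (11.3% to 16.1%) and 27.7% in the knockout library (24.7% to 30.9%). Of 1696 guides against olfactory receptors and other genes not expressed in epithelium, 28.8% (26.6% to 31.0%) and 56.7% (54.3% to 59.1%) were present. The spliceosome stood at 8.09% and 24.3%, and the small ribosomal subunit at 8.59% and 23.4%, both below all 10000 random lists in each library. The proteasome followed at 16.9% and 25.8%, DNA replication at 16.2% and 27.2%, RNA polymerase II and its general factors at 14.3% and 25%, and the large ribosomal subunit at 16.5% and 36.9%. Cytosolic tRNA synthetases, which charge tRNAs with amino acids, stood at 10.0% and 33.8%, and iron-sulfur cluster assembly at 15.9% and 35.2%. These 8 lists were the ones below the lowest 2.5% of random lists in both libraries.

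The area under the ROC curve between 203 essential and 424 unexpressed genes was 0.707 in the control library (95% bootstrap interval over genes 0.666 to 0.749) and 0.805 in the knockout library (0.769 to 0.839). The rate −ln(1 − share present) of essential guides relative to unexpressed guides was 0.429 in the control and 0.387 in the knockout library. Of the 19103 genes with 4 guides, 687 had no guide present in either library, and these included 41 of 203 essential genes (20.2%) against 8 of 424 unexpressed genes (1.89%). All guides were present in both libraries for 43 genes, of which 0 were essential. The difference between the 2 areas was not tested, and it lies beside a difference in the number of guides present.

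**Figure D2:**
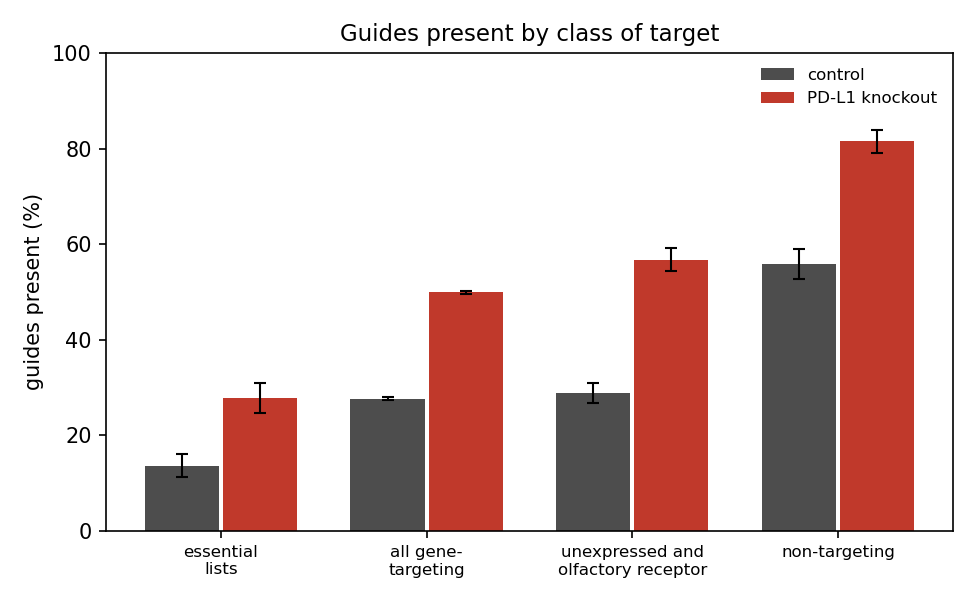
Percent of guides present, at 20 reads or more (vertical axis), for 4 classes of target (horizontal axis) in the control library and the PD-L1 knockout library, with exact 95% binomial intervals. Essential lists were lowest at 13.5% and 27.7%, and non-targeting guides highest at 55.9% and 81.6%.

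CD274 itself, the gene edited in the knockout line, had 2 of its 4 guides present in the control library and 4 in the knockout library, with 1936 and 3851 reads in all. Its guides gave a permutation p of 0.711 (adjusted p = 0.991). Guide abundance does not measure the edited locus, so this does not check the knockout. GPX4, the peroxidase that reduces lipid hydroperoxides, had 1 guide present in the control library (489 reads) and 2 others in the knockout library (772 and 400 reads), with a permutation p of 0.606. SOD2, the mitochondrial superoxide dismutase, had no guide present in the control library and 2 in the knockout library (1304 and 954 reads), and too few retained guides for the test.

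No gene passed the guide-set permutation test. Of 9603 genes tested, 0 were lower and 0 higher in the knockout library after adjustment, and the smallest adjusted p was 0.952. With scores limited to plus or minus 4, the lowest permutation p a gene with 4 guides could reach was 0.00505 toward lower and 0.00298 toward higher, reached by 11 and 3 genes, so no such gene could pass on its own. Without that limit, an alternative chosen after the data were seen, 0 genes were lower and 0 higher, with a smallest adjusted p of 0.620. At an unadjusted p under 0.05 stood 475 genes (258 lower, 217 higher), where 480 would be expected by chance. edgeR's exact test on recovered reads called 0 genes of 18822 in either direction, with 7 at an unadjusted p under 0.05. Presence of guides called 0 of 19103, with 69 lower and 284 higher at an unadjusted p under 0.05, but its smallest p, 0.000327, belongs to the most extreme pattern of 4 guides against 0 and could not pass adjustment. The remaining 9509 genes had fewer than 3 retained guides. On simulated libraries with as few guides present, 0 of 200 genes lost completely from the knockout library were called by the permutation test, so counts of 0 do not exclude differences of single genes.

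The smallest permutation p toward fewer knockout reads, 0.00505, was shared by 11 genes whose 4 guides were all present in the control library, and the 10 with the lowest log2 ratios are named. TAF3, a subunit of the general transcription factor TFIID, had 4221 control reads and 1 knockout read. KLHL38 had 3544 and 2 reads, and TXNDC2, a testis thioredoxin, 4938 and 239. The others were SDCBP2, TSPY1, CUX2, TFAP4, VN1R5, ORAI3 and GAGE12C, of which CUX2 and TFAP4, both transcription factors, kept 2099 and 2434 knockout reads. Toward more knockout reads, PLEKHA2, SSH1 and KPRP shared a permutation p of 0.00298. PLEKHA2 had 1 control read and 2085 knockout reads, SSH1, a cofilin phosphatase, 1 and 2003, and KPRP 0 and 1814. RNF148, PSG1, KATNAL2, SYN1, SCLY, RYR3 and OR4C15 completed the 10, each with 4 guides present in the knockout library and 0 in the control library. None of these 20 genes passed adjustment. The median guide had a log2 ratio of 6.82, and p values are relative to that median.

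The authors' deposited table lists 18823 names, and its guide numbers equal the guides with reads in either library for all 18822 names found in the guide table. The authors' deposited table holds 0 depleted genes at a false discovery rate of 0.05, 0.1 or 0.25, with a lowest rate of 0.92 and 943 genes at an unadjusted p under 0.05. On the enriched side the authors' deposited table holds 2 entries under 0.05 and 895 at an unadjusted p under 0.05. One is the set of non-targeting guides, handled as a gene (false discovery rate 0.00495), and the other is IFITM1, an interferon-induced membrane protein (0.0371). IFITM1 rests on 2 guides with 5499 knockout reads in all against 2 control reads. The depleted side of the authors' deposited table begins with KCTD18, SAR1A, TNFRSF25, F8A2 and HSPB2, followed by TRPC1, KLHL38, SLC35A3, P2RX7 and CNTNAP3B. KCTD18, the first, owes 30232 of its 31527 control reads to a single guide. The enriched side goes on with CPSF3L, DNAAF1, C18orf21, OR5M10, LYRM9, GUCY1A2, TMEM192 and CCDC60. CPSF3L stands there with 2328 control and 7673 knockout reads and a log2 fold change of -9.09 in the authors' deposited table, since its single knockout guide is the largest of that library while its other 2 detected guides were seen in the control only. GPX4 has rank 8631 on the depleted side of the authors' deposited table (p = 0.483) and SLC7A11 rank 210 (p = 0.0123, false discovery rate 0.936), with TXNRD1 ahead of it at rank 184 (false discovery rate 0.92). On the enriched side of the authors' deposited table GPX3 has rank 277 (0.963) and SOD2 rank 478 (0.992). Across the 9602 genes tested here and listed there, the authors' fold changes had a Spearman rho of 0.951 with the median log2 ratios. Both measures come from the same 2 libraries, so a high rho is no independent check. The rho is taken across genes, which are not independent replicates.

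Genes that act in ferroptosis were covered thinly, like the library as a whole, and none passed the test. The 5 ferroptosis lists hold 88 genes, of which 37 were tested (9603 of 19112 over all genes). Over all genes 0 were lower and 0 higher. Adjusted over the list alone, taking the 5 lists as 1, 0 were lower and 0 higher, with a smallest list-adjusted permutation p of 0.240. The lowest permutation p that the score limit allowed was 0.00298, too high for 1 gene among 37 to pass on its own. These counts of 0 therefore do not exclude differences of single ferroptosis genes. At an unadjusted p under 0.05 stood 2 genes. Those 2 were SCLY, which recycles selenium from selenocysteine (permutation p = 0.00648, 0 control reads, 3169 knockout reads), and MSRB1, a selenoprotein methionine sulfoxide reductase (permutation p = 0.0231, 4504 control reads, 1751 knockout reads). Within the 3 tested selenoprotein genes, SCLY was the 1 gene higher when adjusted over that single list alone (list-adjusted permutation p = 0.0195). Over all genes SCLY did not pass (adjusted permutation p = 0.952). Robust rank aggregation, a single spread for all guides and scores without a limit did not call it.

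The ferroptosis defence list had 22.5% of its 80 guides present in the control library (13.9% to 33.2%) and 35.0% in the knockout library (24.7% to 46.5%). Its ratio of rates was 1.69 against 2.14 for all gene-targeting guides, at percentile 16.0 of random lists. Taken by library, its share was at percentile 0.65 of random lists in the knockout library, below the lowest 2.5%, and at 16.4 in the control library. SLC7A11, the cystine transporter that feeds glutathione synthesis, had 3 guides present in the control and 2 in the knockout library, with 4210 and 3354 reads (permutation p = 0.0695, adjusted p = 0.952). AIFM2, which reduces coenzyme Q at the plasma membrane, had 2 and 397 reads, DHODH 1 and 460, and NFE2L2, the transcription factor NRF2, 1 and 447, each with 1 guide present in the knockout library only. MBOAT1 had 1638 control and 0 knockout reads, and NFS1, the cysteine desulfurase, had 0 reads in both. Of the 20 genes in the list, 4 had more guides present in the control library, 13 more in the knockout library and 3 equal numbers.

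The selenoprotein synthesis list stood at 19.4% and 44.4% (ratio 2.72, percentile 60) and iron handling at 20.8% and 45.8% (2.62, percentile 80.3). Genes that promote ferroptosis stood at 28.8% and 50% (ratio 2.04, percentile 48.5). Among these, ACSL4, which activates polyunsaturated fatty acids for insertion into phospholipids, had 3 guides present in each library (2125 and 4186 reads, permutation p = 0.373). LPCAT3 had 2 and 3 guides, and NCOA4, the ferritinophagy receptor, 0 and 3. Superoxide and peroxide detoxification stood at 32.0% in the control library (23.0% to 42.1%) and 40.0% in the knockout library (30.3% to 50.3%), a ratio of 1.32 at percentile 1.59 of random lists. In that list TXNRD1, the cytosolic thioredoxin reductase, had 2175 and 0 reads, TXN 1512 and 0, and PRDX1 917 and 1, each from 1 guide present in the control library only. GPX2 had 0 and 1764 reads and SOD1 2 and 1089. By log2 ratio of the 11 tested members the list was at percentile 4.89.

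Over the 37 lists, the unfolded protein response and ERAD list, whose genes handle misfolded proteins of the endoplasmic reticulum, stood lowest in the knockout library relative to the control. Its 92 guides were present at 32.6% in the control library (23.2% to 43.2%) and 31.5% in the knockout library (22.2% to 42.0%), a ratio of 0.959 at percentile 0.025 of random lists, and its 6 tested genes had a median log2 ratio of -4.38 at percentile 0.22. DDIT3, the stress transcription factor CHOP, had 3 guides present in the control and 1 in the knockout library, while SYVN1, the ubiquitin ligase of ERAD, had 0 and 4. DNAJC3, an endoplasmic reticulum chaperone named after its values were seen, had 4 and 1 guides (4058 and 701 reads). Adjusted over the list alone, DNAJC3 was the 1 gene lower (permutation p = 0.00509, list-adjusted permutation p = 0.0305). It did not pass over all genes (adjusted permutation p = 0.952). Nor did it pass over the list under robust rank aggregation, a single spread or scores without a limit. Coenzyme Q synthesis (41.7% and 43.8%, ratio 1.07, percentile 1.06) and respiratory complex I (35.9% and 48.9%, ratio 1.51, percentile 1.44) were also at the low end by presence, complex I not in 1 of 3 alternatives. By log2 ratio both lists lay inside the central 95% (percentiles 18.7 and 6.76). Taken by library, these stood high in the control (percentiles 97.6 and 99.1) and inside the central 95% in the knockout library (21.9 and 39.8), whereas the unfolded protein response and ERAD list stood at 84.8 and 0.05. Growth suppressors stood at the high end, with 26.7% and 60% (ratio 2.95, percentile 98.0), 24 of 30 genes having more guides in the knockout library and 0 fewer, against 11971 and 2545 of all 19112 genes. Their place outside the central 95% was lost in 2 of 3 alternatives, at percentile 93.3 for the lowest. Autophagy, SWI/SNF and Polycomb, and apoptosis lists also had 0 genes with fewer guides in the knockout library, and lay inside the central 95%. Unexpressed tissue genes stood nearly as high by presence, at 28% and 60% (ratio 2.79, percentile 95.5), with 35 of 50 genes higher and 5 lower. Presence therefore hardly sets growth suppressors apart from unexpressed genes. Olfactory receptors stood at the high end by presence (28.9% and 56.3%, percentile 99.4). By log2 ratio they lay inside the central 95%, at percentile 75.55 (28.0 to 99.0 over 8 alternatives).

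In all, 6 of the 37 lists lay outside the central 95% of random lists by presence and 4 of 36 by log2 ratio, where 1.85 of 37 would be expected by chance. The 4 by log2 ratio were the unfolded protein response and ERAD list, the small ribosomal subunit (percentile 1.06), growth suppressors (99.4) and RNA polymerase II with its general factors (97.6). The small ribosomal subunit rests on 3 tested genes of 32 and RNA polymerase II on 4 of 28, and by presence of all members they lay inside, at percentiles 70.7 and 16.4, on the other side of the middle. Over 8 alternatives RNA polymerase II lost that place in 6 (44.2 to 97.6), growth suppressors in 2 (84.2 to 99.9) and the small ribosomal subunit in 1 (0.795 to 3.81). A call adjusted over the list alone came from 2 of 37 lists, SCLY and DNAJC3 above. By chance 1.85 would be expected if every list could give a call. With scores limited, a single gene could not pass on its own in the longest lists, so 1.85 is an upper value. This comparison does not decide whether the 2 calls exceed chance. Lists tied to PD-L1 lay inside by presence: control of PD-L1 protein at percentile 84.2, interferon and JAK-STAT signalling at 45.0, antigen presentation at 31.4 and other immune checkpoints at 55.5. So did EGFR and MAPK signalling (71.1), YAP and TEAD (61.6), autophagy (94.2), apoptosis (85.9), the squamous lineage (24.3) and the NRF2 axis (23.9). STAT2 had 0 guides present in the control and 3 in the knockout library, SPOP 3 and 0, and CDKN2A, the tumour suppressor of the p16 and ARF proteins, 3 and 3.

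**Figure D3:**
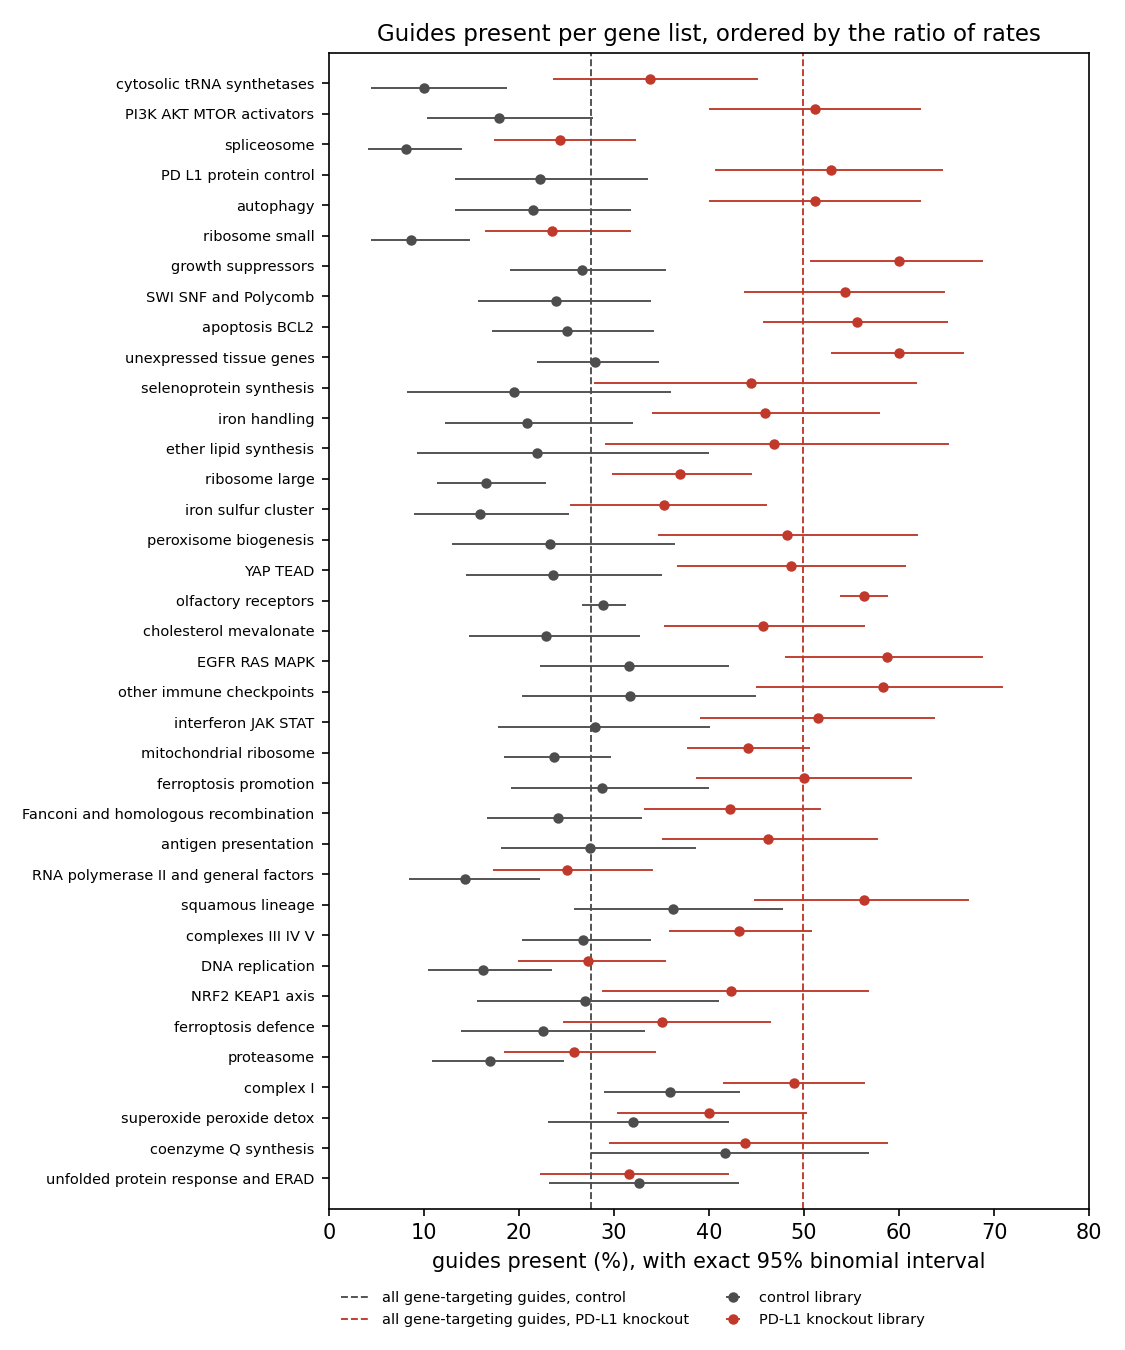
Percent of guides present (horizontal axis) for each of 37 gene lists (vertical axis) in the control library and the PD-L1 knockout library, with exact 95% binomial intervals, ordered by the ratio of rates; dashed lines mark all gene-targeting guides (27.6% and 49.9%). The unfolded protein response and ERAD list is at the bottom, with 32.6% and 31.5%, and cytosolic tRNA synthetases at the top, with 10.0% and 33.8%.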

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

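The tests of depth, founding units and low reads below, and the test of chance among lists, were chosen after the results were seen; the others were set before. Non-targeting guides, which the gene comparisons leave out, stood apart from gene-targeting guides in both libraries: 55.9% were present in the control library (52.8% to 59.0%) and 81.6% in the knockout library (79.1% to 84.0%), against 27.6% and 49.9% of gene-targeting guides. Guides against olfactory receptor and other unexpressed genes, at 28.8% and 56.7%, also stood below the non-targeting guides. The cause was not tested. Their mean reads were 2.27 and 2.35 times those of gene-targeting guides, and they took 2.89% and 2.98% of all reads as 1.29% of guides.

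The control library held fewer present guides than the knockout library, 28.0% against 50.3%. Lower depth was argued against: thinning the knockout reads to the control's total left 50.2% of guides present. Fewer founding units, either cells or template molecules, stay open: the ratio of estimated units (2.4) was 1.13 times the ratio of rates given by absent guides (2.13), but the second read peak lay at 1.86 times the first in the control and 1.62 times in the knockout library (1.65 and 1.64 with smoothing over 30 in place of 50 reads), where whole units would put it at 2. The PD-L1 genotype cannot be told apart from the library, with 1 library per genotype.

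Low read counts in the control library followed the knockout library. Among guides under 20 control reads, those with 1600 or more knockout reads had a mean of 1.2 control reads and those with 0 knockout reads 0.197, a ratio of 6.07 (95% bootstrap interval 5.62 to 6.55), which is consistent with reads carried over from the knockout library. A shared starting pool predicts a rise in guides present too, and the share present was 2.00 times as high (1.91 to 2.08), 43.7% against 21.9%. A share that starts at 21.9% has no room to rise by a ratio of 6.07. This comparison therefore cannot tell a shared starting pool from carried-over reads. In the mirrored direction, mean knockout reads were 0.247 at 0 control reads and 0.438 at 1600 or more. No biological explanation was tested for this pattern.

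The unfolded protein response and ERAD list had the lowest ratio of rates, 0.959. In 1.9% of 1000 random families of 37 lists (19 families) the most extreme list was as extreme, which argues against chance among the lists examined, although the presence measure itself was chosen after the data were seen. Leaving out each of its 23 genes in turn gave percentiles of at most 0.275, so a single gene does not carry it. Whether PD-L1 knockout cells depend on this pathway was not tested: 1 library per genotype cannot decide it, and replicate libraries of both lines would. A difference between these 2 libraries unrelated to PD-L1 stays as open.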

How the results depend on the processing

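With 1 library per condition, leaving out a replicate, averaging duplicates and limma across columns were not possible, and were not run. The planned trend correction used a kernel-smoothed mean in place of loess. The edgeR test, scores without a limit, the presence tests and their thresholds of 5 and 100 reads were chosen after seeing the data. The counts of 0 genes lower and 0 higher held under all 14 alternatives, with 7 to 600 genes at an unadjusted p under 0.05 in both directions together. That is no sign of robustness: the permutation test called 0 of 200 simulated genes lost completely, and the alternatives were not simulated. Scaling by the sum of all guides, which drops the centring on 6.82, split those as 239 lower and 0 higher, against 258 and 217. At a threshold of 0.25, 1 ferroptosis gene (SCLY) was higher adjusted over the 5 ferroptosis lists taken as 1. Over the alternatives GPX4 had a permutation or exact p from 0.0668 to 1 and a lowest adjusted p of 0.867, and SLC7A11 a p from 0.0236 to 0.846. Lists outside the central 95% by log2 ratio fell to 2 with no filter on guides and to 2 with random lists not matched; the cause was not tested. The unfolded protein response and ERAD list stayed below the lowest 2.5% under all alternatives for both measures. The knockout library's area under the ROC curve was 0.740 with all genes as the reference; the cause was not tested. Without non-targeting guides, the share at 0 was 56.5% in the control and 44.1% in the knockout library. Robust rank aggregation recomputed from the deposited values called 0 genes higher, against 2 entries in the authors' deposited table. Of these, the non-targeting set was not tested here and IFITM1 had a recomputed false discovery rate of 0.971. The recomputation ranked guides by their log2 ratio, and how the authors ranked guides is not given in the sources used here. The 2 counts may therefore come from unlike tests, and the difference does not check the authors' calls. Lists with a call over the list alone numbered 0 to 5, and robust rank aggregation and a single spread each called 3 lists that shared 0 of the genes SCLY and DNAJC3. By presence, growth suppressors lost their place outside the central 95% in 2 of 3 alternatives and complex I in 1. Thinning the knockout reads to the control's total left 50.2% of guides present, so the read total does not set that share.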

Other observations

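The shares of guides present and the estimates of units were chosen after the data were seen, and the tests of clone size and of the neighbours of CD274 were written before their results. Guides against squamous lineage genes stood at 36.3% in the control library and 56.3% in the knockout library, inside the central 95% of random lists (percentiles 94.7 and 85.2), where JUP, the junction protein plakoglobin, had 0 and 3 guides present and CTNNB1 2 and 1. Mitochondrial ribosome guides stood at 23.7% and 44.1%, and respiratory complexes III, IV and V at 26.7% and 43.2%, also inside the central 95% in each library, while cytosolic ribosome guides lay below the lowest 2.5%. Cholesterol and mevalonate synthesis stood at 22.8% and 45.7%, peroxisome biogenesis at 23.2% and 48.2%, ether lipid synthesis at 21.9% and 46.9%, the Fanconi and homologous recombination genes at 24.1% and 42.2%, and SWI/SNF and Polycomb genes at 23.9% and 54.3%. PI3K, AKT and MTOR activators stood at 17.9% in the control library, at percentile 2.46 of random lists, and 51.2% in the knockout library, at percentile 58.1. Their ratio of rates was at percentile 97.4, just inside the central 95%, and outside it in 1 of 3 alternatives.

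If the first read peak is taken as 1 founding unit, the estimates are 27946 in the control and 67038 in the knockout library, or 1.46 and 3.51 per gene. The stated 20000000 cells at a multiplicity below 0.3 would give up to 6000000 infected cells per line, or 77.5 per guide, and the estimates are 0.466% and 1.12% of that bound. One hypothesis is that each unit was a clone of cells whose size followed its growth, so that essential guides with 1 unit would have fewer reads. Among guides with reads near the first peak in the knockout library, the median was 423.5 reads for 144 essential guides and 413 for 488 unexpressed guides, a ratio of 1.03 (95% bootstrap interval 0.956 to 1.08), and 0.991 (0.905 to 1.07) in the control library. Such a ratio decides nothing, since clones with in-frame repair could grow normally.

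Another hypothesis was a local change of copy number or fitness around CD274. Its 100 nearest genes in RefSeq order had 27.3% of guides present in the control and 51.3% in the knockout library. The ratio of rates was 2.26, at percentile 65.5 of 675 windows of as many neighbouring genes (1.74 to 2.74 in the central 95%). Guide presence over these 100 genes as a set was therefore not unusual. Guide abundance does not measure the locus itself, and a change limited to the closest genes could be lost among 100. The hypothesis is thus not decided by these values.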
